A study of Mus musculus with 11 samples.

How the data were processed

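RNA was measured in 11 libraries of CD11b-positive myeloid cells, enriched with antibodies and magnetic beads from subcutaneous mouse tumours 4 days after local irradiation at 15 Gy. Per the labels, the host mice were wild type (WT, 3 libraries), lacked Tlr9 (TLR9KO, 4 libraries) or carried an MxCre transgene with a floxed Stat3 gene (STAT3KO, 4 libraries), all on a C57BL/6 background. Nothing in the labels states that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

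The deposited files hold 1 RPKM value (reads per kilobase of transcript, scaled to the mapped reads) per gene symbol, per the file headers, for 22068 symbols written to 2 decimals. The header of 1 file, TLR9KO replicate 4, names no unit, and its values have the same range and steps as those of the other 10. The submitters' processing notes name CASAVA 1.7, TopHat 1.3.1, Bowtie 0.12.7 and Partek, without a version for Partek, and the mouse build mm9. The gene annotation, the read total used as the denominator and the treatment of reads that map to several places are not given in the sources used here. Near-identical genes, such as the hemoglobin genes and members of the Slfn family, can therefore share reads. In the files, 25 symbols are written as calendar dates and were kept under those names, and 3534 symbols have a value of 0 in every library.

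Depth was estimated from the steps of the values. A single read in a gene of known length adds a fixed RPKM, and 27 to 47 microRNA genes per library, with values from 0.1 to 2 RPKM and lengths from GENCODE M21, were scanned over depths from 10 to 90 M reads. At the best depth, 75.0% to 97.1% of these values lay within 0.15 of a whole number of reads, against 14.7% to 25.0% at the median depth scanned. The depth found was lowest in WT replicate 1 and highest, at 53.45 M reads, in STAT3KO replicate 1. At these depths, 1 RPKM in a gene of 2 kb stands for 60 to 107 reads. Shorter genes, and genes far below 1 RPKM in a group, rest on fewer reads, and their counting error was not measured. Depths were used for description only. RPKM values are not counts, and no count model was fitted.

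Values were analysed as log2(RPKM + 1), without further scaling, for the 10557 genes with a mean of at least 1 RPKM over the 11 libraries. Log2 differences are on this scale, which understates changes of low genes. A linear model with the 3 group means was fitted to all 11 libraries with limma 3.58.1 (lmFit, contrasts and eBayes with trend) in R 4.3.3. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Errors beside RPKM values are standard deviations, and those beside log2 differences are the model's moderated standard errors. On simulated data with 200 changed genes, drawn from those with a mean log2(RPKM + 1) above 2, 2-fold changes were recovered in 92%, 87% and 95% of the genes for STAT3KO minus WT, TLR9KO minus WT and STAT3KO minus TLR9KO. For 4-fold changes these shares were 100%, 99% and 100%, and the false calls were 3.52%, 3.12% and 2.99%. The simulated genes varied independently and held no trend with GC content or length, so these rates may not hold for the real data. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.

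The comparisons, tests, gene lists, named-gene rule and most alternatives were chosen before the data were examined. The lists with at least 4 tested members, 20 in number, were tested with camera at its preset correlation of 0.01, adjusted over the 60 tests of the 3 comparisons. Members past the threshold were also counted with the adjustment over the list alone. On simulated data a list moved by 1 log2 unit was called in each comparison, and 0 of the 19 other lists were, with the adjustment over the lists of 1 comparison. The simulated genes varied independently, so this does not show how often lists of correlated genes are called falsely. In the data the estimated correlation was 0.72 for the interferon-stimulated genes and 0.756 for the hypoxia and glycolysis genes. No camera call held with an estimated correlation. The median, the mean and the test of a list differed in sign for 4, 3 and 5 lists in STAT3KO minus WT, TLR9KO minus WT and STAT3KO minus TLR9KO.

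The genes named for each comparison are Stat3 and Tlr9, then the 6 largest rises and 6 largest falls among genes past the threshold whose groups do not overlap and whose higher group mean is at least 5 RPKM. For each list with a member past the threshold or a called test, up to 4 members with the smallest p were added. Genes named outside this rule are said to be chosen after their values were seen.

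Gene neighbours of Tlr9 and Stat3 were taken from a RefSeq table of assembly GRCm38.p6, to which 99.1% of the tested genes were matched by symbol or synonym. That assembly is not the build of the files, and no coordinates are given. Genes within 5 Mb of a target were compared with all others by Fisher's exact test. Among the genes past the threshold, the share that fell near Tlr9 was compared with that elsewhere after the data had been seen, at 3 windows with and without the correction described below, 6 tests adjusted together. The overlap of both knockouts against WT was set beside 100 simulations of unchanged groups and beside the overlap of independent lists.

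The alternatives fixed in advance were a pseudocount of 0.1, no filter, a mean of at least 5 RPKM, median-ratio and quantile scaling, limma without trend, array weights, the replicate number as a block, fits of only the 2 groups compared and fits without each library. For lists, an estimated correlation and the rotation test fry were tried, and for neighbours windows of 2 and 10 Mb. A correction for GC content and length was added after the data had been seen, in 1 specification. In each library, the deviation of each gene from its mean was freed of its loess trend (degree 1, span 0.4, 2 rounds) on transcript GC content and log2 length, taken from the longest GENCODE M21 transcript for 98.8% of the tested genes. It was also run with the replicate block. Of the 8 lists set up after the data had been seen, 1 is not reported here.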

Results

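Gene expression was measured in CD11b-positive myeloid cells from irradiated subcutaneous tumours of WT (n = 3), TLR9KO (n = 4) and STAT3KO (n = 4) mice. CD11b is an integrin of monocytes, macrophages, neutrophils and some dendritic cells. Tlr9 encodes an endosomal receptor for unmethylated CpG DNA, and Stat3 a transcription factor activated by cytokine receptors. Each library had a value above 0 for 15123 to 16237 gene symbols. The log2 values correlated across genes at 0.959 to 0.993 between libraries of one group and at 0.932 to 0.976 between groups, where genes are not independent replicates.

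The targeted genes were low in the libraries labelled as their knockouts. Stat3 was 19.7, 15.7, 19.6 and 17.8 RPKM in the 4 STAT3KO libraries, 58.5 to 68.8 RPKM in TLR9KO and 70.7 to 76.1 RPKM in WT. The STAT3KO mean of 18.2 ± 1.85 RPKM (SD, n = 4) was 24.9% of the WT mean of 73.1 ± 2.78 RPKM (n = 3), with a log2 difference of -1.95 ± 0.09 and a limma adjusted p of 2.44e-06. Tlr9 was 3.53, 6.15, 7.70 and 5.71 RPKM in the TLR9KO libraries and 20.5, 41.6 and 28.9 RPKM in WT. The TLR9KO mean of 5.77 ± 1.72 RPKM was 19% of the WT mean of 30.3 ± 10.6 RPKM (log2 -2.19 ± 0.37, limma adjusted p = 0.00193). Tlr9 in STAT3KO ranged from 19.2 to 61.1 RPKM and did not pass the test against WT (limma adjusted p = 0.995). Gene-level values do not show which exons the remaining reads cover.

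**Figure D1:**
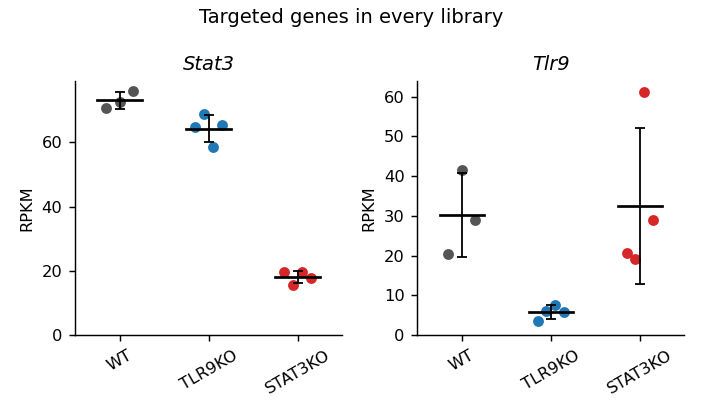
RPKM of Stat3 (left) and Tlr9 (right) in every library of WT (n = 3), TLR9KO (n = 4) and STAT3KO (n = 4). Points are libraries, horizontal bars group means and whiskers 1 SD. Stat3 lies between 15.7 and 19.7 RPKM in STAT3KO, below every other library, and Tlr9 between 3.53 and 7.70 RPKM in TLR9KO, below every other library.

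The comparison of STAT3KO with WT asks how the myeloid cells of irradiated tumours differ when Stat3 is deleted. Apoe, a lipid carrier abundant in tissue macrophages, rose from 636 ± 156 to 3127 ± 930 RPKM (log2 2.28 ± 0.24). Trem2, a lipid-sensing macrophage receptor, rose from 110 ± 4.55 to 348 ± 37.0 RPKM (1.65 ± 0.12), and Cx3cr1, the fractalkine receptor, from 1.18 ± 0.56 to 21.9 ± 12.2 RPKM (3.28 ± 0.38). Socs3, a feedback inhibitor induced by STAT3, fell from 110 ± 4.97 to 23.4 ± 4.99 RPKM (log2 -2.21 ± 0.19, limma adjusted p = 2.18e-05). Nos2, the inducible nitric oxide synthase, fell from 83.2 ± 33.2 to 10.7 ± 1.99 RPKM (-2.80 ± 0.21).

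In all, 4648 of the 10557 genes tested passed the threshold, of which 3083 rose and 1565 fell, and 645 of them changed at least 2-fold (388 up, 257 down). With median-ratio scaling the split was 2167 up and 2286 down, and with the GC and length correction 2111 up and 1921 down. Of the 4585 called genes that could be corrected, 3057 kept their call and direction, and 1507 lost their call. The differences followed GC content (Spearman -0.244 across genes) and length (-0.296). The median log2 difference of all genes was 0.095, and -0.018 with median-ratio scaling, a shift of over 0.1. The groups did not overlap for 47.7% of the genes, against 5.7% by chance. The largest rises were Ctla2b, a protein related to the propeptides of cathepsins (log2 3.53), Cx3cr1, the iron exporter Slc40a1 (2.85), the G-protein regulator Rgs1 (2.58), 1500012F01Rik (2.49) and Ms4a7 (2.49). The largest falls were 1600029D21Rik (-4.39), the carbonic anhydrase Car4 (-3.77), Pdcd1lg2, which encodes the PD-1 ligand PD-L2 (-3.65), the adhesion molecule Cdh1 (-3.42), the arginine transporter Slc7a2 (-3.25) and Ccdc80 (-3.13).

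Of 24 tested STAT3 target genes, 3 rose, 8 fell and 13 did not pass, and adjusted over the list alone 4 rose and 8 fell. Besides Socs3, falls included the interleukin 4 receptor chain Il4ra (-1.36 ± 0.15), the NF-kB cofactor Bcl3 (-1.11 ± 0.14) and the hypoxia-inducible factor Hif1a (-1.07 ± 0.14). The list test did not pass (camera adjusted p = 0.0748). Among 19 inflammatory cytokines and NF-kB targets, 2 rose and 6 fell (4 and 7 adjusted over the list alone), with the cytokine Il6 at -1.66 ± 0.27 and the prostaglandin synthase Ptgs2 at -1.42 ± 0.30. That list test did not pass either (camera adjusted p = 0.0663). Alternative activation markers went both ways, with 4 up and 6 down of 18, and the same counts adjusted over the list alone. The scavenger receptor Msr1 rose (1.38 ± 0.12), and the chemokine Ccl17 (-2.88 ± 0.45) and fibronectin Fn1 (-2.64 ± 0.39) fell. Of 23 angiogenesis and matrix genes 7 rose and 6 fell, also adjusted over the list alone. The urokinase Plau rose (0.99 ± 0.12), while the growth factors Pgf (-2.84 ± 0.39), Areg (-2.64 ± 0.38) and Tgfb1 (-0.92 ± 0.09) fell.

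Of 19 antigen presentation genes 2 rose and 5 fell (1 and 5 adjusted over the list alone), with the class II transactivator Ciita at -1.80 ± 0.43 and the invariant chain Cd74 falling from 6170 ± 1861 to 2524 ± 781 RPKM, a call lost without WT replicate 2 (limma adjusted p = 0.0694). Among 27 Toll-like receptor pathway genes 0 rose and 7 fell, also adjusted over the list alone, including Tlr6 (-0.61 ± 0.11), Tlr4 (-0.64 ± 0.12) and its co-receptor Cd14 (-0.95 ± 0.22). Of 30 interferon-stimulated genes 9 rose and 0 fell (8 and 0 adjusted over the list alone), led by Ifit3 (1.59 ± 0.32). That share is near the 3083 of all 10557 genes that rose, and the list test did not pass (camera adjusted p = 0.0915). The mean log2 value of the list was 4.405 in WT replicate 1 and 5.218 and 5.186 in WT replicates 2 and 3. In STAT3KO it ran from 5.121 to 6.139. Of 20 hypoxia and glycolysis genes 0 rose and 6 fell (0 and 3 adjusted over the list alone), with the phosphofructokinase Pfkp at -1.33 ± 0.15. This was the one list called (camera adjusted p = 0.0251; adjusted p = 0.933 with an estimated correlation), and its call was lost without WT replicate 3 (0.127) or STAT3KO replicate 4. Of 18 p53 targets 9 rose and 2 fell, also adjusted over the list alone, with the growth differentiation factor Gdf15 up (1.56 ± 0.16) and the antiproliferative gene Btg2 down (-1.70 ± 0.23). Of 22 proliferation genes 4 rose and 0 fell (2 and 0 adjusted over the list alone), including the replication clamp Pcna (1.06 ± 0.13). Of 13 immediate early and heat shock genes 3 rose and 4 fell (3 and 5 adjusted over the list alone), with Egr1 at -1.79 ± 0.23 and Atf3 at 0.85 ± 0.16.

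Of 14 macrophage markers 10 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.0543, and 0.0228 with the GC and length correction; adjusted p = 0.933 with an estimated correlation). Of 9 inflammatory monocyte markers 3 rose and 2 fell, also adjusted over the list alone, with Ly6c2 up (2.08 ± 0.50) and the matrix proteoglycan Vcan down (-1.35 ± 0.47), a call lost without WT replicate 2 (limma adjusted p = 0.111). Of 8 dendritic cell markers 0 rose and 2 fell, also adjusted over the list alone, including the integrin Itgax (-2.19 ± 0.29). Of 13 neutrophil markers 0 rose and 2 fell, also adjusted over the list alone, Il1r2 (-1.74 ± 0.16) and Trem1 (-2.22 ± 0.29). The median log2 difference of the list was 0.31. S100a9 (2.04 ± 0.77, limma adjusted p = 0.0521) and Retnlg (1.57 ± 0.74, limma adjusted p = 0.111) were higher without passing, with their highest values in STAT3KO replicate 2. Markers of other cell types also differed. Of 6 fibroblast markers 4 rose and 0 fell, also adjusted over the list alone, with the collagen Col1a1 at 9.47 ± 2.52 RPKM in STAT3KO and 1.11 ± 0.38 RPKM in WT. Of 6 erythroid and platelet markers 1 rose and 4 fell, also adjusted over the list alone. The hemoglobin gene Hba-a1 was 59.8 ± 33.2 RPKM in WT and 8.58 ± 11.7 RPKM in STAT3KO, where replicate 2 had 26.1 RPKM and the other 3 libraries 1.42 to 3.99 RPKM. The platelet factor Pf4 rose (1.91 ± 0.48). Among the other platelet genes of the list, Ppbp passed the filter on mean RPKM, while Itga2b, Gp9 and Gp1ba did not. The rise of Pf4 alone therefore does not show platelet RNA. Of 9 T and NK cell markers 0 rose and 2 fell (0 and 1 adjusted over the list alone), of 4 endothelial markers 1 fell, also adjusted over the list alone, and of 13 melanocyte markers none passed. The rises of Pf4 (limma adjusted p = 0.0655), Ms4a4c, Tk1 and Cdk1 and the falls of Rela and Hk2 did not pass with the GC and length correction.

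**Figure D2:**
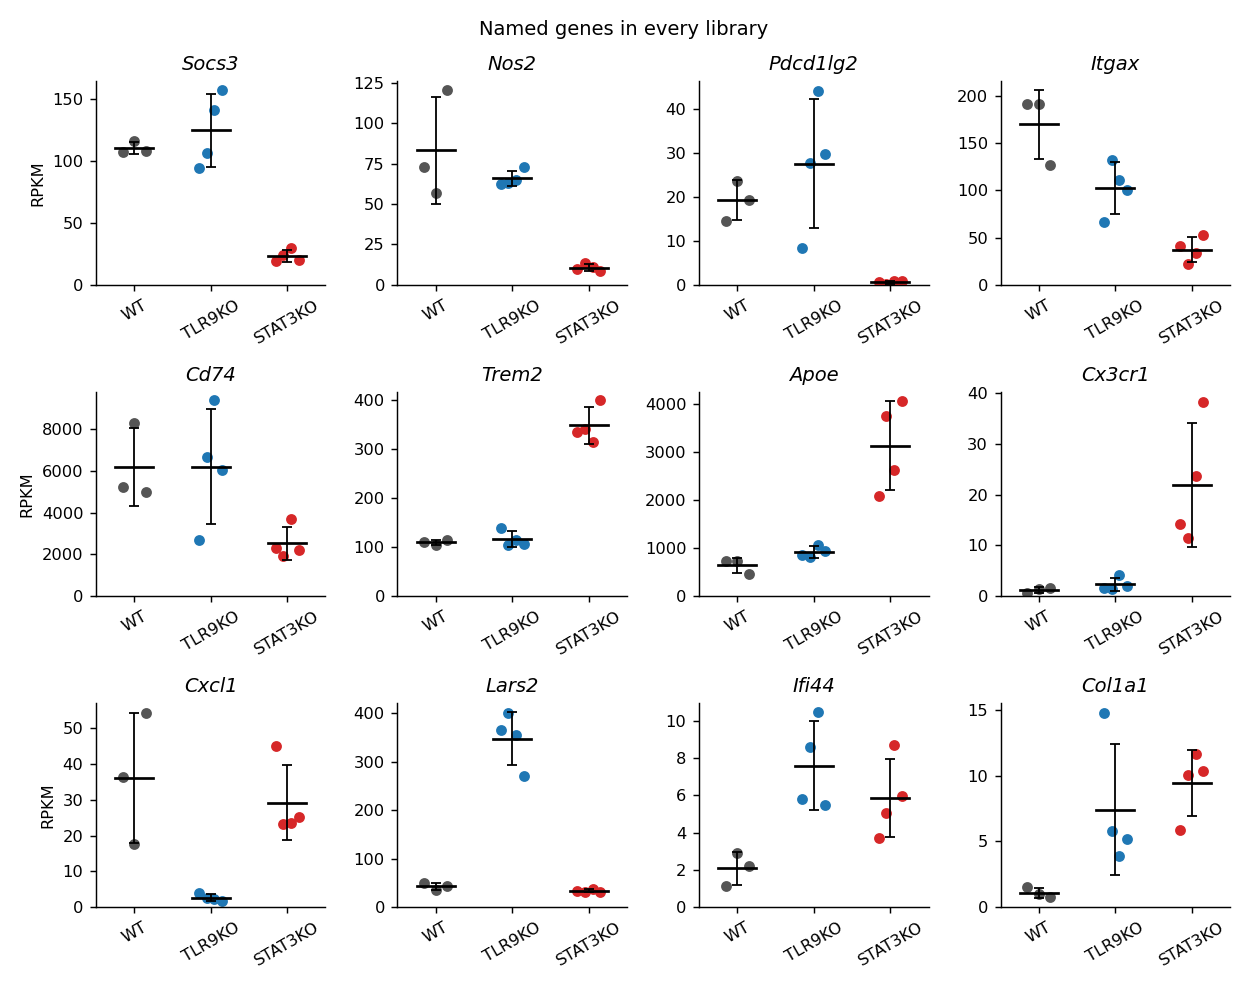
RPKM of 12 named genes in every library of WT (n = 3), TLR9KO (n = 4) and STAT3KO (n = 4), each panel with its own linear axis from 0. Points are libraries, bars group means and whiskers 1 SD. Socs3, Nos2 and Pdcd1lg2 are low and Trem2, Apoe and Cx3cr1 high in STAT3KO, Cxcl1 is low and Lars2 high in TLR9KO, and Ifi44 and Col1a1 have lower means in WT than in either knockout.

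The comparison of TLR9KO with WT asks how the same cells differ when Tlr9 is missing. Lars2, the mitochondrial leucyl-tRNA synthetase, rose from 42.7 ± 6.59 to 347 ± 54.3 RPKM (log2 2.99 ± 0.14, limma adjusted p = 1.93e-06), and the calmodulin-like gene Calml4 from 0.72 ± 0.24 to 7.87 ± 0.66 RPKM (2.38 ± 0.12). Cxcl1, a neutrophil chemoattractant, fell from 36.1 ± 18.2 to 2.63 ± 0.99 RPKM (-3.26 ± 0.35). The interferon-inducible genes Slfn8 (2.23 ± 0.24), Slfn4 (2.20 ± 0.54) and Mndal (1.87 ± 0.31) rose, as did the chemokine Ccl8 (2.11 ± 0.24). The 3 largest falls were the hemoglobin genes Hba-a1, at 0.82 ± 0.51 RPKM in TLR9KO against 59.8 ± 33.2 RPKM in WT (-4.89 ± 0.71), Hba-a2 (-4.70) and Beta-s (-4.41), followed by Cxcl1 and the hemoglobin genes Hbb-b1 (-2.89) and Hbb-b2 (-2.70).

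In all, 3229 genes passed the threshold, 2107 up and 1122 down, of which 230 changed at least 2-fold (177 up, 53 down). The groups did not overlap for 36.1% of the genes, against 5.7% by chance. The differences followed the GC content of the transcripts, with a Spearman correlation across genes of -0.552. The median log2 difference was 0.39 in the 20% of genes with the lowest GC content and -0.19 in the 20% with the highest. With the GC and length correction 1654 genes passed, 942 up and 712 down, and 1182 of the 3183 called genes that could be corrected kept their call and direction. The genes changed at least 2-fold then numbered 76. Median-ratio scaling gave 1680 up and 1544 down, and without WT replicate 1 the count was 1989.

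Of 30 interferon-stimulated genes 9 rose and 0 fell, also adjusted over the list alone, including Ifi44 (1.48 ± 0.28), the oligoadenylate synthetase Oas2 (0.94 ± 0.21) and the RNA sensor Ifih1 (1.01 ± 0.25). The list was called as higher (camera adjusted p = 0.0119, and 0.000351 with the correction; adjusted p = 0.933 with an estimated correlation), but not without WT replicate 1 (0.137). Of 20 hypoxia and glycolysis genes 0 rose and 3 fell (0 and 2 adjusted over the list alone), with the enolase Eno1 at -0.69 ± 0.18. That list was called as lower (camera adjusted p = 0.0306; adjusted p = 0.933 with an estimated correlation), but not without WT replicate 3 (0.127) or TLR9KO replicate 3 (0.137). Of 6 erythroid and platelet markers 0 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.0123, and 0.0627 with the correction; adjusted p = 0.933 with an estimated correlation). Among 19 inflammatory genes 1 rose and 3 fell (1 and 2 adjusted over the list alone). Il18 rose (1.58 ± 0.20) and Il6 fell (-1.02 ± 0.27). Of 18 alternative activation markers 2 rose and 1 fell (1 and 1 adjusted over the list alone), with Msr1 up (1.08 ± 0.12) and Fn1 down (-1.51 ± 0.39).

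Of 24 STAT3 target genes only Fos passed (0.72 ± 0.18), and 0 did adjusted over the list alone. Of 23 angiogenesis genes 1 rose and 2 fell (0 and 1 adjusted over the list alone), with Tgfb1 at -0.88 ± 0.09. Of 27 Toll-like receptor pathway genes 4 rose and 3 fell (2 and 2 adjusted over the list alone), among them the adaptor Tirap (0.39 ± 0.09). Of 18 p53 targets 4 rose and 2 fell, also adjusted over the list alone, with Sesn2, a stress-induced regulator of growth signalling, at -0.65 ± 0.11. Of 13 immediate early genes 3 rose and 2 fell, also adjusted over the list alone. Of 14 macrophage markers none passed, nor did any of 8 dendritic cell or 13 melanocyte markers. Of 13 neutrophil markers 0 rose and 2 fell (0 and 1 adjusted over the list alone), Trem1 (-1.15 ± 0.29) and Il1r2 (-0.51 ± 0.16). Of 9 monocyte markers 1 rose and 1 fell, also adjusted over the list alone. Of 6 fibroblast markers 4 rose and 0 fell, also adjusted over the list alone, including Col1a1 (1.85 ± 0.35) and the proteoglycan Bgn (1.24 ± 0.23). Calls of B2m, Ly96, Ticam1, Rela, Pcna, Cdkn1a, Ccng1, Polk, Nfkbiz, Hbegf, Plau, Ifit1, Retnla, Pfkp, Tpi1, Ms4a4c and Nr4a1 were lost with the correction, and B2m, Ly96 and Polk also changed sign. Without WT replicate 1, 19 of the 52 calls of named genes were lost, among them Slfn4 (limma adjusted p = 0.0545), Ifih1 (0.0627), Fn1 (0.0656), Fos (0.0647), Tirap (0.052), Eno1 (0.0706) and Il1r2 (0.121). Without WT replicate 3, 16 were lost, again with Eno1 and Il1r2, and the fall of Il6 did not pass without WT replicate 2 (limma adjusted p = 0.057).

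**Figure D3:**
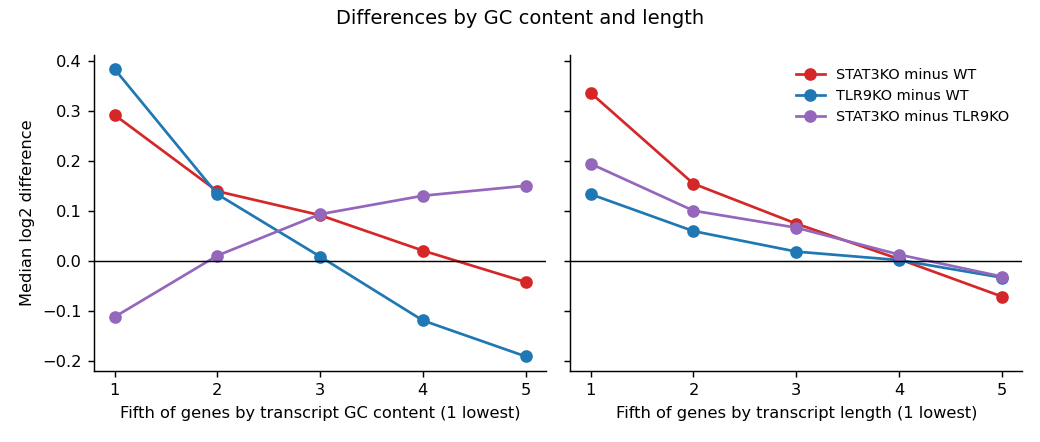
Median log2 difference of the genes in 5 equal bins by GC content (left) and by length (right) of the longest annotated transcript, for the 3 comparisons of WT (n = 3), TLR9KO (n = 4) and STAT3KO (n = 4). In TLR9KO minus WT the median falls from 0.39 in the lowest GC bin to -0.19 in the highest.

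The comparison of STAT3KO with TLR9KO sets both knockouts against each other without the WT libraries in the difference. Npy, neuropeptide Y, was 26.8 ± 7.32 RPKM in STAT3KO and 0.04 ± 0.04 RPKM in TLR9KO (log2 4.71 ± 0.19, limma adjusted p = 2.73e-07). Cxcl1 (3.04 ± 0.32), Slc40a1 (3.00 ± 0.44), Cx3cr1 (2.72 ± 0.35), AA465934 (2.62 ± 0.22) and Ctla2b (2.48 ± 0.22) were also higher in STAT3KO. The largest falls were 1600029D21Rik (-4.93), Pdcd1lg2 (-3.97), Lars2 (-3.31), Ccdc80 (-3.24), Slc7a2 (-2.98) and Ccl17 (-2.86).

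In all, 2409 genes passed, 1410 up and 999 down, with 295 changed at least 2-fold (124 up, 171 down). Median-ratio scaling gave 919 up and 1189 down, and array weights raised the count to 3807. Without TLR9KO replicate 4 the count was 1581. The groups did not overlap for 27.0% of the genes, against 2.9% by chance. Of 14 macrophage markers 5 rose and 0 fell, also adjusted over the list alone, including Trem2 (1.57 ± 0.11), Apoe (1.73 ± 0.23) and Cd68 (0.66 ± 0.12). The list was called as higher (camera adjusted p = 0.0119; adjusted p = 0.933 with an estimated correlation). Of 19 antigen presentation genes 0 rose and 7 fell (0 and 8 adjusted over the list alone), with Ciita at -1.58 ± 0.40, H2-Aa at -1.34 ± 0.39 and Cd74 at -1.21 ± 0.35. That list was called as lower (camera adjusted p = 0.00435; adjusted p = 0.933 with an estimated correlation). Of 19 inflammatory genes 1 rose and 4 fell (1 and 5 adjusted over the list alone), with Nos2 (-2.53 ± 0.20), Ptgs2 (-2.14 ± 0.28) and the cytokine Il1b (-2.54 ± 0.55) down. It was also called as lower (camera adjusted p = 0.0251; adjusted p = 0.933 with an estimated correlation), but not without TLR9KO replicate 1 (0.0762).

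Of 24 STAT3 target genes 3 rose and 8 fell, also adjusted over the list alone, with Socs3 at -2.36 ± 0.17 and Myc at 1.04 ± 0.14. Of 18 alternative activation markers 3 rose and 8 fell (4 and 8 adjusted over the list alone), with the beta-glucan receptor Clec7a at -1.98 ± 0.28 and the chemokine Ccl24 at 1.36 ± 0.18. Of 23 angiogenesis genes 4 rose and 6 fell, also adjusted over the list alone, including Angpt2 (1.45 ± 0.20) and Pgf (-2.46 ± 0.36). Of 18 p53 targets 6 rose and 1 fell (8 and 2 adjusted over the list alone), with Gdf15 at 1.38 ± 0.15. Of 30 interferon-stimulated genes only Cxcl9 passed (-2.48 ± 0.71), and 0 did adjusted over the list alone. Of 13 immediate early genes 0 rose and 5 fell, also adjusted over the list alone, including Junb (-1.01 ± 0.19). Of 27 Toll-like receptor pathway genes 3 rose and 5 fell (4 and 7 adjusted over the list alone), with Tlr4 at -0.75 ± 0.11. Of 22 proliferation genes 4 rose and 0 fell (1 and 0 adjusted over the list alone), and of 20 hypoxia genes only Pfkp passed (-0.81 ± 0.14), also adjusted over the list alone. Of 13 neutrophil markers 1 rose and 2 fell, also adjusted over the list alone, with Retnlg up (2.30 ± 0.69). Retnlg was 67.56 RPKM in STAT3KO replicate 2 and 4.06 to 9.61 RPKM in the other 3, and its rise was 1.52 without that library (limma adjusted p = 0.0408) but lost its call without TLR9KO replicate 2 (limma adjusted p = 0.0807). Of 6 fibroblast and 6 erythroid and platelet markers none passed over all genes, and adjusted over the list alone 3 of the latter rose. Without TLR9KO replicate 4, 13 of the 62 calls of named genes were lost, among them Ciita, H2-Aa, Cd74 and Cxcl9. With the GC and length correction 4 were lost, Mki67, Tk1, Bax and Ccr2.

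**Figure D4:**
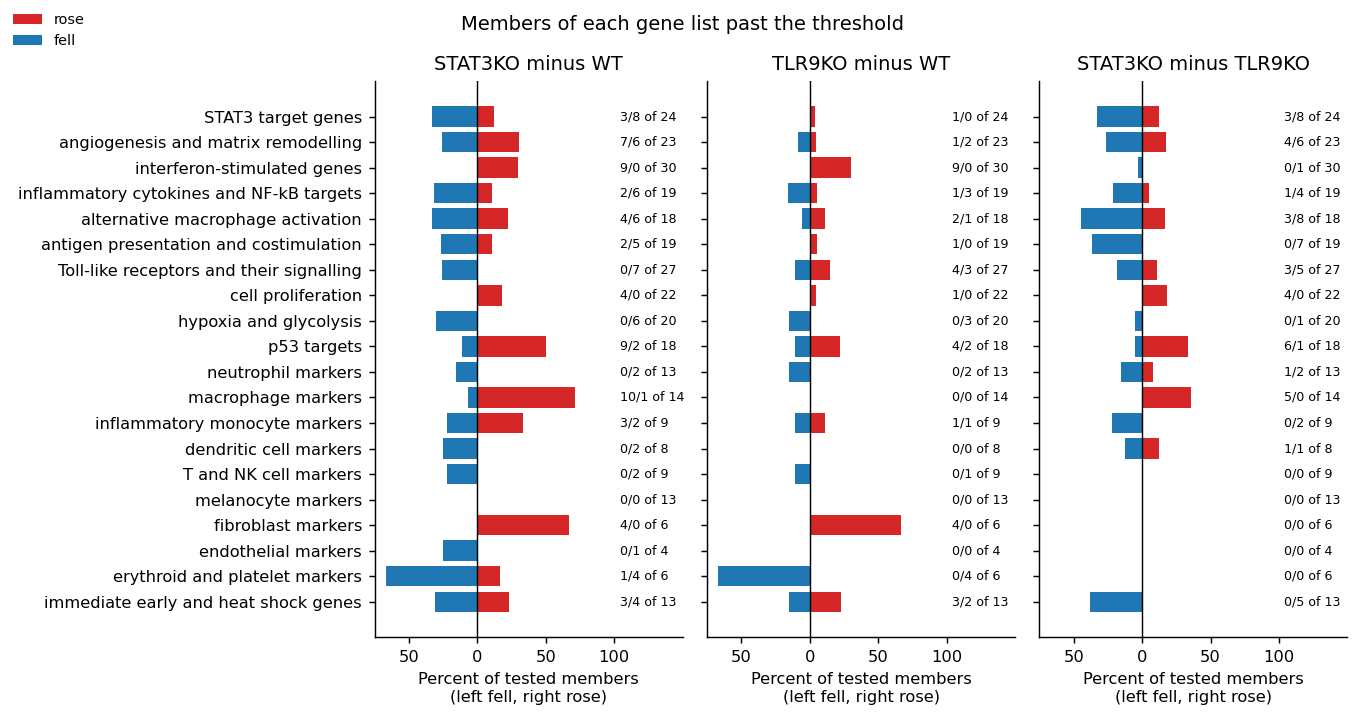
Percent of the tested members of each gene list that rose (red, right) or fell (blue, left) past the threshold in each of the 3 comparisons of WT (n = 3), TLR9KO (n = 4) and STAT3KO (n = 4), with the counts risen and fallen and the tested members at the right. Of 14 macrophage markers 10 rose and 1 fell in STAT3KO minus WT, and of 30 interferon-stimulated genes 9 rose in each knockout against WT. Neither list was called by camera in STAT3KO minus WT.

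Against the same WT libraries, 1627 genes rose and 708 fell in both knockouts, and 42 went in opposite directions. Independent lists would share 615 and 166 genes, and simulated unchanged groups that share the WT libraries gave 0, which follows from their having no changes to call and does not measure the overlap that shared controls bring to real changes. The log2 differences correlated across genes at 0.644, against a simulated mean of 0.525 (range -0.631 to 0.981). Their covariance was 0.144 against a simulated 0.019 (range -0.02 to 0.078). With the GC and length correction 783 genes rose in both and the covariance was 0.093. The 708 shared falls became 1104 with median-ratio scaling, 376 without WT replicate 1 and 329 with the correction and the replicate block. The 42 genes in opposite directions became 23 with the correction, and 12 without WT replicate 3. The 3 WT libraries cannot be split into 2 control sets of 2, so part of the excess may come from the shared controls.

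Genes around the targets, where DNA of the strain in which an allele was made can remain, were changed about as often as other genes. Within 5 Mb of Tlr9 on chromosome 9, 33 of 109 tested genes passed in TLR9KO minus WT, or 30.3% against 30.5% elsewhere (Fisher's exact p = 1). The 33 genes near Tlr9 fell more often than other called genes (69.7% against 34.5%, Fisher's exact adjusted p = 0.000344, chosen after the data had been seen). With the GC and length correction that was 54.5% of 22 against 42.9% (adjusted p = 0.286). Within 5 Mb of Stat3 on chromosome 11, 50 of 135 passed in STAT3KO minus WT, or 37.0% against 44.1% (Fisher's exact p = 0.116). Neighbours were taken from assembly GRCm38.p6.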

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

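Only the search for single libraries apart from their group and the shares of genes changed within 2 and 5 Mb of Tlr9 were planned. All other tests in this part were chosen after the results were seen. Other groupings of the libraries gave fewer changed genes. For each comparison, 1 of the 35 splits of its libraries, the real one, gave as many genes, the lowest share that so few libraries allow. The real counts were 4648 in STAT3KO minus WT, 3229 in TLR9KO minus WT and 2409 in STAT3KO minus TLR9KO, and the highest of the other splits were 1184, 1252 and 0. Every other split mixes the groups and so widens the spread within them, and lower counts follow from any difference between the groups. The splits cannot tell genotype from a batch that follows the groups.

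In TLR9KO minus WT the log2 differences fell with GC content (Spearman -0.552 across genes), and WT and TLR9KO libraries deviated in opposite directions, from 0.068 to 0.493 in WT and from -0.483 to -0.266 in TLR9KO. Of the 3183 called genes that could be corrected, 1182 kept their call and direction after the correction. The trends it removed do not account for these calls. It had 1 specification, with transcripts that may differ from the submitters' annotation, so bias it models poorly could remain. For the 1991 genes that lost their call, bias tied to GC content and length remains a candidate cause. Their median size fell from 0.457 to 0.175 log2 while the median standard error went from 0.110 to 0.097. The correction also removes any real difference that follows GC content or length, so a biological difference between the genotypes stays open for these genes.

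Lars2 and Calml4, both on chromosome 9 with Tlr9, led the rises in TLR9KO. The GC content and length trends that the correction removed do not account for Lars2, whose log2 difference was 3.09 after it. Without the pair, tested genes within 20 Mb of Tlr9 went from 217 to 216, and farther ones of chromosome 9 from 363 to 362. The pair therefore do not both lie within 20 Mb of Tlr9. Genes of chromosome 9 were frequent among those of smallest p in TLR9KO (72 Fisher's exact tests adjusted together, over 4 sizes, 3 gene sets and 3 comparisons with and without the correction), which is the pattern itself and no evidence for a cause. DNA of another strain around Tlr9, carried along with the knockout allele, remains a candidate explanation that could not be decided: without Lars2 and Calml4, 4.63% of the genes within 20 Mb of Tlr9 were among the 200 of smallest p in STAT3KO minus TLR9KO after the correction, against 3.87% of the farther genes of chromosome 9, and 0 of 16 such Fisher's exact tests passed (lowest adjusted p = 0.895). Within 5 Mb 30.3% of the genes changed against 30.5% elsewhere, and within 2 Mb 37.5% against 30.5% (Fisher's exact p = 0.345), and those within 2 Mb fell more often than elsewhere (77.8% against 34.7%), but not past the threshold after the correction (75% of 8, Fisher's exact adjusted p = 0.123), in a region of higher median GC content (0.547 against 0.497). Too few genes remain to exclude a local cause, and an effect of the receptor itself on Lars2 stays open.

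STAT3KO replicate 2 held neutrophil granule transcripts far above the other 3 STAT3KO libraries, such as Ngp at 95.0 RPKM (others up to 0.3), Camp at 21.9 (up to 0.12) and Lcn2 at 58.0 (up to 1.09), with Chi3l3 at 1043.37 against 35.1 to 68.5 RPKM. A mislabelled library is argued against by its Stat3 value of 15.7 RPKM, the lowest of all libraries. RNA of neutrophils or their precursors could not be decided, since 4 of 7 other precursor genes were highest in this library (one-sided exact binomial p = 0.0706). Elane and Mpo were at most 0.19 RPKM in every library, too low to decide it. The mean log2 value of the neutrophil markers was 3.686 in it against 1.596 to 1.894 in the other STAT3KO libraries. That list holds Ngp, Camp and Lcn2 themselves, and its member Csf3r was lowest in this library among the STAT3KO libraries. A glucocorticoid response in this library is a candidate explanation, since 8 of 10 induced genes other than the first ones noticed were highest in it (one-sided exact binomial p = 0.000416), as were Fkbp5 at 100.43 RPKM against 10.7 to 12.0 and Tsc22d3 at 153 RPKM. These genes move together in 1 library and are not independent, so the p overstates the evidence, and the 2 explanations do not exclude each other.

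Single libraries stood apart from the other 3 of their group in 30 of 344 searches, where chance gives about 17. The search used groups of 4 libraries, so the 3 WT libraries were not searched. WT replicate 2 had a mean log2 value of the sex-linked genes of 1.739, against 1.274 and 1.277 in replicates 1 and 3. Its Spearman correlation with GC content was 0.068, against 0.451 and 0.493 in replicates 1 and 3. In STAT3KO replicate 2 these were also S100a9 (149.79 RPKM), Retnlg (67.56), Hba-a1 (26.1), Hbb-b1 (4.87), Clec7a (27.21, low), Hif1a (19.58, low), the mean log2 value of the neutrophil markers (3.686) and that of the sex-linked genes (1.626, low). In STAT3KO replicate 3 they were H2-DMb1 (181.24 RPKM), Rela (35.43), Btg2 (41.08), Ms4a4c (175.35), Mndal (55.13), Lck (2.06), Klrd1 (2.49) and Il2rb (6.30). STAT3KO replicate 1 was apart in Col1a2 (3.26 RPKM, low) and Cxcl1 (44.99), and replicate 4 in Ctla2b (30.76 RPKM) and the mean log2 value of the skeletal muscle markers (0.616).

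TLR9KO replicate 1 was apart in Car4 (19.07 RPKM), Bgn (5.92), Col1a2 (10.26) and Cd68 (1089.5). TLR9KO replicate 3 was apart in Lck (2.18 RPKM), Klrd1 (2.08) and the mean log2 value of the alternative macrophage activation genes (5.443, low). TLR9KO replicate 4 was apart in Hbb-b2 (0.61 RPKM) and Hbb-b1 (0.17), both near 0.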

How the results depend on the processing

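The GC and length correction, alone or with the replicate block, was chosen after seeing the data, and all other alternatives before. Counts of changed genes stayed within 1.5 times except in these cases. For TLR9KO minus WT (3229) the correction gave 1654 genes, and 1068 with the replicate block, and the genes changed at least 2-fold went from 230 to 76 with the correction. For STAT3KO minus TLR9KO (2409) array weights gave 3807. Without each library in turn the counts ran from 3673 to 4878 in STAT3KO minus WT, from 1989 (without WT replicate 1) to 3595 in TLR9KO minus WT, and from 1581 (without TLR9KO replicate 4) to 2709 in STAT3KO minus TLR9KO. Genes that rose in both knockouts (1627) numbered 783 with the correction and 518 with correction and block, and 1077 to 1737 without single libraries, lowest without WT replicate 1. Genes that fell in both (708) numbered 1104 with median-ratio scaling and 329 with correction and block, and 376 to 783 without single libraries, lowest without WT replicate 1. Genes in opposite directions (42) numbered 23 with the correction, 17 with correction and block, and 12 (without WT replicate 3) to 61 without single libraries. The covariance of 0.144 became 0.093 with the correction and 0.094 with correction and block, and 0.130 to 0.184 without single libraries, where the correlation ran from 0.606 to 0.689. The correction removes trends by construction, and for the other shifts the cause was not tested.

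Calls of gene lists depended on the method. In STAT3KO minus WT (1 called) there were 4 with median-ratio scaling, 3 with the replicate block, 5 with the correction, 6 with correction and block, 0 with an estimated correlation, 3 by fry for direction and 14 by fry for mixed changes, and 0 to 8 without single libraries. In TLR9KO minus WT (3 called) there were 0 with an estimated correlation, 1 by fry for direction and 9 for mixed changes, and 2 to 4 without single libraries. In STAT3KO minus TLR9KO (3 called) there were 0 with an estimated correlation and 9 by fry for mixed changes, and 2 to 9 without single libraries. The highest counts came without STAT3KO replicate 3 in each comparison. Without STAT3KO replicate 4, 2 list calls were lost over the 3 comparisons, the hypoxia and glycolysis list in STAT3KO minus WT among them. The cause was not tested.

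Signs turned for Klrd1 in STAT3KO minus WT with correction and block (-0.30), and in TLR9KO minus WT for B2m (-0.16 with the correction, -0.14 with block), Ly96 (-0.054 and -0.064) and Polk (-0.002 and -0.004). A turned sign was counted only where the main fit or the alternative called the gene or list. Over the other values of named genes, 4670 kept their side of the threshold, 343 lost their call and 58 gained one. Over the list tests, 1014 kept their side of the threshold, 24 lost and 102 gained their call. Those on the same side include genes and lists not called in either fit, whose direction may differ. The shares of genes changed near the targeted loci did not differ past the threshold from those elsewhere at any window, while the share of called genes that fell near Tlr9 did at all 3 windows without the correction (adjusted p from 0.000344 to 0.0022) and at 0 with it.

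Replicate numbers did not pair the libraries throughout: 4 of 10 pairs with one number in different groups had correlated deviations above 0.1 (range -0.291 to 0.492). These were the pairs of replicate 1 (0.492, 0.339 and 0.181) and STAT3KO with TLR9KO replicate 3 (0.446). Libraries of different numbers also shared deviations, such as TLR9KO replicate 3 and WT replicate 2 (0.533). What links libraries across groups was not tested. With the replicate block 4074, 2662 and 1879 genes passed in STAT3KO minus WT, TLR9KO minus WT and STAT3KO minus TLR9KO. Depth limits little for a 2 kb gene at 1 RPKM, which stands for at least 60 reads, but more for shorter genes and lower values.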

Other observations

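All list tests in this part were chosen after the results were seen: 8 lists were set up at that point and tested in 3 comparisons, 24 camera tests adjusted together, and their calls do not hold with an estimated correlation (lowest adjusted p = 0.605). Among 21 complement and phagocytosis genes 4 rose and 5 fell in STAT3KO minus WT, with the scavenger receptor Cd36 up (1.48) and the complement gene C4b down (-1.53). In TLR9KO minus WT 3 rose and 0 fell, and in STAT3KO minus TLR9KO 4 rose and 5 fell (camera adjusted p = 0.144, 0.907 and 0.0722 in this order of comparisons).

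Of 76 ribosomal protein genes 57 rose and 0 fell in STAT3KO minus WT, 33 and 2 in TLR9KO minus WT and 32 and 0 in STAT3KO minus TLR9KO. With the correction these were 34 and 5, 18 and 3, and 21 and 2. Of 82 oxidative phosphorylation subunits 58 rose and 2 fell, 33 and 4, and 26 and 0, in the same order. With the correction these were 29 and 10, 11 and 7, and 16 and 2, and the camera adjusted p was 0.05, 0.274 and 0.05. Lysosome genes were called lower in TLR9KO minus WT (1 rose and 8 fell of 28, camera adjusted p = 0.0449, and 0.0688 with the correction), with the galactosidase Glb1 at -1.32, but not in STAT3KO minus WT (3 and 4, adjusted p = 0.624) or STAT3KO minus TLR9KO (5 and 1, adjusted p = 0.124). Neutrophil precursor genes were not called in any comparison (adjusted p = 0.962, 0.182 and 0.367), nor were glucocorticoid-induced genes (0.0909, 0.0585 and 0.962).

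Melanocyte transcripts were abundant in every group, with Dct at 256 ± 127 RPKM in WT, 228 ± 96.4 in TLR9KO and 379 ± 82.9 in STAT3KO (SD), in cells enriched for CD11b. The values may therefore include RNA of other cells. The mean log2 value of the melanocyte markers was lowest in WT replicate 2 (4.268), TLR9KO replicate 3 (4.445) and STAT3KO replicate 3 (4.807) within their groups. That of the hypoxia and glycolysis genes was lowest in the same libraries (6.870, 6.399 and 6.628). Whether the amount of such RNA drives the hypoxia list was not tested. Xist was listed at 0 in all 11 libraries. Of 4 tested Y-linked genes 2 rose and 0 fell in STAT3KO minus WT, 3 rose and 0 fell in TLR9KO minus WT, and 0 rose and 1 fell in STAT3KO minus TLR9KO, with the same counts adjusted over the list alone. Ddx3y was 6.62 to 8.42 RPKM in TLR9KO, 4.02 to 4.98 in STAT3KO and 3.4 to 6.51 in WT.

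Phgdh, the first enzyme of serine synthesis (-1.78), Trib3 (-1.49), Asns, the asparagine synthetase (-1.46), and the amino acid transporter Slc7a5 (-1.25), 4 genes named after their values were seen, were lower in TLR9KO than in WT. Slc7a5 also fell in STAT3KO minus WT (-1.23). The hypothesis is that a lower amino acid stress (ATF4) programme in TLR9KO may underlie this. In a list of other genes of this programme without these genes, 1 of 21 rose and 7 fell. The list was called as lower (camera adjusted p = 8.34e-05, and 4.13e-05 with the GC and length correction), but not with an estimated correlation (adjusted p = 0.605). Against the hypothesis at the level of mRNA, Atf4 itself was the gene that rose (0.49), while its protein was not measured. Ddit3, a target of the same programme, did not pass (-0.03, and -0.47 with the correction, adjusted p = 0.0718) and does not decide it. In STAT3KO minus WT both Atf4 (0.93) and Ddit3 (0.98) rose, the latter not past the threshold with the correction (0.40, adjusted p = 0.0751). The list was also called lower in STAT3KO minus WT (3 rose and 5 fell, adjusted p = 0.0479, and 0.0688 with the correction) and higher in STAT3KO minus TLR9KO (5 and 1, adjusted p = 0.0475, and 0.106).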
